A study of Mus musculus with 39 samples.

How the data were processed

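RNA-seq measured transcript levels in mouse pineal gland and in pineal tumours of engineered mice. Per the labels, total RNA was extracted with the AllPrep RNA Micro Kit and libraries were made with the TruSeq Stranded Total RNA kit, which keeps transcripts without a poly(A) tail. The labels describe 39 samples: 3 samples of pineal gland dissected at embryonic day 15 (E15), 2 at postnatal day 1 (P1), 2 at postnatal day 21 (P21), 5 tumours of genotype Crx Dgcr8 p53, 6 of Crx MycT and 19 of Crx Rb p53. The remaining 2 samples carry a title of Crx Rb p53 and a genotype label of Crx MycT, and were left in no group. The pineal samples have the genotype label Crx GFP, and the labels state no sorting of cells.

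The authors aligned the reads with STAR to the mm10 assembly per the submitters' processing notes; the aligner version, the counting tool, the gene annotation and the use of strand in counting are not given in the sources used here. The authors deposited raw read counts per gene for 51988 gene symbols and FPKM values, that is fragments scaled to gene length and library size, for 48757 symbols. The count values were whole numbers with a different total in each library. The deposited FPKM table was used only for alternatives to the count test.

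Each table has 39 columns, and 10 of them could be tied to a labelled group by name: E15 pineal libraries 1 to 3, P1 pineal libraries 1 and 2, and 5 Rb p53 tumours named 53, 55, 88, 89 and 98. The other 29 columns carry names that no label repeats and were not used here. The tumour numbers are not the replicate numbers of the labels, so these 5 tumours could not be tied to an age of induction, and they could include the 2 samples whose title and genotype differ. P21 pineal, Dgcr8 p53 tumours, MycT tumours, all comparisons between tumour models, induction ages, the position of tumours on a scale from E15 to P21 and the genes shared by all tumour models were therefore not analysed here. Of the comparisons fixed before the data were examined, 2 could be run: P1 against E15 pineal, and Rb p53 tumour against pineal. The baseline of the tumour comparison, set before the data were examined as the equal-weight mean of all pineal ages, became the equal-weight mean of the 2 ages at hand.

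The total count per library lay between 29477109 and 53124500 reads. P-values measure only the spread between the samples, and no label says whether the libraries of a group come from separate animals. Xist (109 to 297 CPM) and the Y gene Ddx3y (39.3 to 68.8 CPM) are both present in each pineal library, so a pineal library may pool glands of both sexes, and the SD of the pineal groups may then be one between pools. Each tumour has transcripts of Xist or of the Y gene, with the other under 1 CPM. Values are given as CPM, that is counts scaled to a common library size after TMM scaling, as mean ± SD over the n libraries of a group. A fold against a group with no count was computed against a floor of 3 counts over all libraries of that group and is written as a lower bound. This bound covers counting error only.

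Genes were kept by filterByExpr with the 3 groups, which left 21806 tested genes. A single edgeR quasi-likelihood model (edgeR 4.0.16 in R 4.3.3) was fitted to all 10 libraries in 3 groups, so that the groups share one estimate of the spread. P values were adjusted by the Benjamini-Hochberg method over all tested genes within a comparison, and a gene was called at an adjusted p under 0.05. The log2 fold change is given with its standard error (SE), computed as the size of the log2 fold change divided by the square root of the quasi-likelihood F. Positions are those of GENCODE release M21 on GRCm38 (mm10), matched by gene symbol.

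The lists of genes, 30 in all, were fixed before the data were examined: genes shared by rods and cones, rod, cone, pinealocyte, neural progenitor, S phase, G2 and M phase, ribosome biogenesis (known MYC targets), p53 targets, host transcripts of microRNAs, oncofetal let-7 targets, synaptic vesicle, brain neuron, astrocyte, oligodendrocyte, ependyma and choroid plexus, microglia and macrophage, lymphocyte, endothelium, mural cell, fibroblast and meninges, erythroid, pigment cell, other retinal cells, interferon response, antigen presentation, hypoxia, immediate early, mitochondrial transcripts and replication-dependent histones. After the data were seen, 3 lists were added: epidermis, skeletal muscle, and bone and cartilage. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the correlation between genes preset to 0.01, and again with a correlation estimated for each list. The rotation test fry was run beside it: its p tests whether the genes of a list move, on balance, in one direction, and its mixed p whether they change in either direction; neither compares a list with other genes. List p-values were adjusted over the fixed lists, and over the 3 added lists apart. For each list, genes called after adjustment over all genes were counted, and also those called when p-values were adjusted over the list alone.

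The rule for named genes was also fixed before the data were examined. It took the genes that the labels name, then the 3 largest increases and 3 largest decreases between ages and the 6 largest in each direction between tumour and pineal, and then the 3 members with the smallest p of each called list and of the shared photoreceptor, rod, cone and pinealocyte lists. The largest changes were taken among called genes with a mean log2 CPM of at least 3 and no overlap between the libraries of the sides compared. Predicted genes, pseudogenes, mitochondrial, ribosomal protein and sex-linked genes were left out of that part. Other genes named in the text were chosen after their values were seen, as examples of a counted group.

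Alternatives set before the data were examined were size factors of DESeq2 (RLE) in place of TMM, no filter and a stricter filter on low counts (at least 1 CPM in at least 5 of the 10 libraries), DESeq2 1.42.0, limma voom with quality weights, and limma-trend on log2(FPKM + 1), on log2(FPKM + 0.1) and on genes of mean FPKM of at least 1. Also set then were a fit on the compared groups alone, the replicate number as a block, each pineal age alone as baseline, and each library left out in turn. Chosen after the data were seen were fits without libraries that hold markers of other tissues, a count without epidermis and erythroid genes, and list tests with libraries left out.

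The tests were first tested on simulated data with the group sizes and spread of these libraries, in which 200 genes were changed 2-fold or 4-fold. For P1 against E15, edgeR recovered 5% of 2-fold and 47% of 4-fold changes, with 2 false calls among 54. For tumour against pineal it recovered 19% and 73%, with 10 false calls among 102. DESeq2 recovered more, 74% and 88% of the 4-fold changes, with 97 false calls among 192 and 96 among 231. limma voom recovered 42% and 72% of the 4-fold changes, with 0 false calls among 47 and 10 among 98.

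Overlaps between the comparisons were set against 10 simulations with no difference between groups, since both comparisons use the same pineal libraries. The number of genes called between tumour and pineal was set against other divisions of the 10 libraries into groups of 5. These divisions were first drawn with the ages kept apart, which counted the exchange of the real sides as a separate division; they were then redrawn with each division counted once. That change was made after the first draw had been seen. Some tests were judged unable to decide only after their values had been seen. These were the tests of a segment gain around Mycn and of RLE scaling for photoreceptor genes. The tests of skin in the E15 dissections and of a lower share of pineal cells at E15 were judged so as well.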

Results

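Transcript levels were compared across 10 RNA-seq libraries of mice. Of these, 3 were of pineal gland at embryonic day 15 (E15) and 2 of pineal gland at postnatal day 1 (P1). The other 5 were of pineal tumours, placed in the Crx Rb p53 group by their column names alone. They could include the 2 samples whose title and genotype label differ. The pineal gland makes melatonin, and its pinealocytes share part of their gene programme with the photoreceptors of the retina. Total counts were 29477109 to 51846290 reads in E15 pineal, 37896734 to 39217958 in P1 pineal and 36285845 to 53124500 in the tumours. Across genes, which are not independent replicates, Pearson correlations of log2 CPM were 0.978 to 0.983 between E15 libraries, 0.975 between the P1 libraries and 0.907 to 0.981 between tumours. They were 0.932 to 0.958 between E15 and P1 libraries, 0.773 to 0.841 between E15 and tumour libraries and 0.822 to 0.880 between P1 and tumour libraries. The first principal component held 79.7% of the variance and set all 5 tumours apart from all 5 pineal libraries. Marker levels of neighbouring tissues differed between libraries of a group. The mean log2 CPM of the skeletal muscle list was 4.64 in P1 pineal library 2 and 1.47 in library 1, and that of the brain neuron list was 4.92 in tumour 89 and 0.32 to 1.55 in the other tumours. The brain neuron mean was also 4.62 in P1 pineal library 1 and 3.77 in library 2, so leaving out P1 library 2 does not remove all such markers.

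The genes that the genotype labels name were examined in each group first. Crx, a transcription factor of photoreceptors and pinealocytes, had 194 ± 127 CPM in E15 pineal (SD, n = 3), 931 ± 40.7 in P1 pineal (SD, n = 2) and 1240.4 ± 167 in the tumours (SD, n = 5). Trp53, which encodes the tumour suppressor p53, had 58.6 ± 10.4, 41.7 ± 18.6 and 9.003 ± 1.28 CPM in the same order. Rb1, which encodes the retinoblastoma protein, had 64.1 ± 5.64, 69.02 ± 2.49 and 34.1 ± 6.75 CPM. Dgcr8, a part of the microRNA processing complex, had 50.1 ± 1.97, 46.3 ± 0.0776 and 83.7 ± 30.7 CPM, and Myc, a transcription factor that promotes growth, 21.3 ± 5.83, 14.001 ± 1.497 and 7.61 ± 4.50 CPM. Crx lies on chromosome 7 at 15865947 to 15879968, Trp53 on chromosome 11 at 69580359 to 69591873 and Rb1 on chromosome 14 at 73183673 to 73325822 (mm10).

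**Figure D1:**
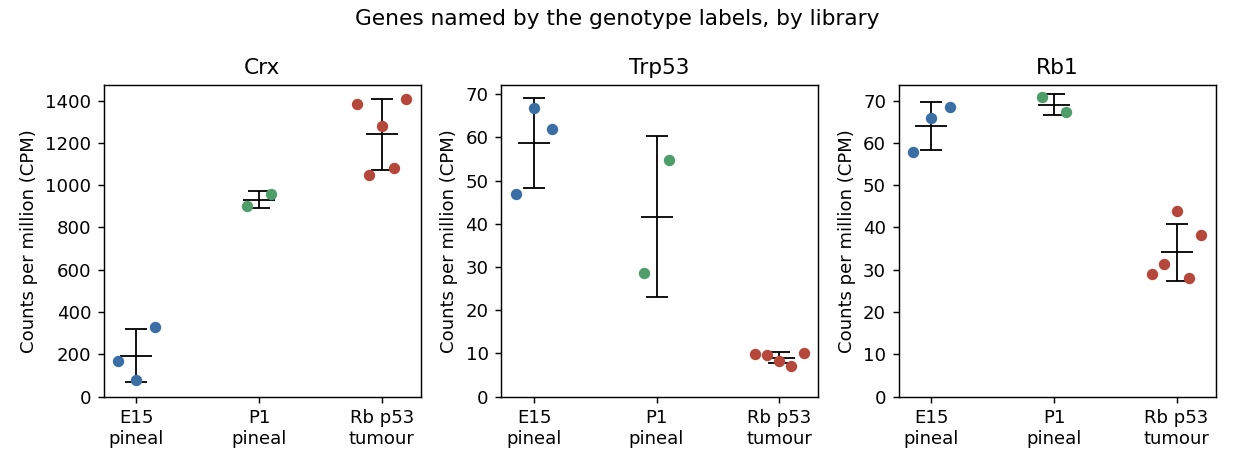
CPM of Crx, Trp53 and Rb1 (vertical axes) in each library of E15 pineal (n = 3), P1 pineal (n = 2) and Rb p53 tumour (n = 5). Each point is a library and the bar shows the mean ± SD. The tumours average 9.003 CPM of Trp53 and 34.1 CPM of Rb1, against 58.6 and 64.1 CPM in E15 pineal.

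The comparison of P1 with E15 pineal asked how expression changes around birth, and genes of photoreceptors and of melatonin synthesis were higher at P1. Of 24 genes shared by rods and cones, 15 rose and 1, the retinol dehydrogenase gene Rdh12, fell. Adjusted over the list alone, 19 rose and 1 fell. Tulp1, needed for protein transport in photoreceptors, rose from 8.07 ± 2.10 CPM (SD, n = 3) to 119 ± 41.7 CPM (SD, n = 2), a log2 fold change of 3.89 (SE 0.29, adjusted p = 8.33e-04). Cplx4, a complexin of ribbon synapses, rose by 5.27 (SE 0.40) and the retinal homeobox gene Rax by 4.80 (SE 0.49). Crx rose by 2.27 (SE 0.45, adjusted p = 0.0421), with every P1 library above every E15 library. The list as a whole was higher than other genes (camera adjusted p = 1.65e-21), and adjusted p = 0.0356 with an estimated correlation. The call of Crx was lost without E15 library 1 (adjusted p = 0.169), E15 library 2 (0.0548), P1 library 1 (0.191) or P1 library 2 (0.179) and in a fit on both ages alone (0.0525), within a range of 5.35e-04 to 0.191 over its alternatives. Of the shared photoreceptor genes, 8 were called higher without E15 library 1, without E15 library 2 and without P1 library 2.

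Rod genes showed the same direction with fewer calls. Of 20 rod genes, 5 rose and none fell, and 9 rose adjusted over the list alone. Pde6g, a subunit of the rod phosphodiesterase, rose from 0.768 ± 0.0862 to 155 ± 20.2 CPM, a log2 fold change of 7.65 (SE 0.43, adjusted p = 1.97e-04). The rod outer segment gene Rom1 rose by 3.11 (SE 0.21) and the rod channel subunit Cngb1 by 3.04 (SE 0.38). The list test gave a camera adjusted p = 2.35e-11, and adjusted p = 0.116 with an estimated correlation. Of the rod genes, 3 were called without E15 library 1, E15 library 2, E15 library 3 or P1 library 2, each left out in turn.

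Of 17 cone genes, 7 rose and none fell, and 12 rose and 1 fell adjusted over the list alone. Gnb3, a G protein subunit of cones, rose from 21.4 ± 7.93 to 254 ± 9.28 CPM, a log2 fold change of 3.57 (SE 0.38, adjusted p = 0.00269). The cone phosphodiesterase gene Pde6c rose by 4.62 (SE 0.54) and the complexin gene Cplx3 by 2.98 (SE 0.42). The camera adjusted p was 4.56e-10, and adjusted p = 0.0356 with an estimated correlation. The number of called cone genes was 3 without E15 library 1, E15 library 2 or P1 library 1 and 2 without P1 library 2. The call of Cplx3 was lost without E15 library 1 (adjusted p = 0.0524) or P1 library 2 (0.0671), and that of Pde6c with the replicate number as a block (0.0518); the ranges over alternatives were 1.06e-07 to 0.0671 and 4.18e-13 to 0.0518.

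Of 19 pinealocyte genes, 7 rose and none fell, and 13 rose adjusted over the list alone. Aanat, the penultimate enzyme of melatonin synthesis, rose from 0.0529 ± 0.0223 to 14.4 ± 2.68 CPM, a log2 fold change of 7.96 (SE 0.84, adjusted p = 0.00255). Asmt, the last enzyme of that pathway, rose by 7.60. The adrenergic receptor genes Adra1b and Adrb1 rose by 4.21 (SE 0.36) and 2.47 (SE 0.26). The camera adjusted p was 6.23e-15, and adjusted p = 0.0285 with an estimated correlation. The epidermis, erythroid and skeletal muscle lists, which mark other tissues, had mean log2 CPM of 6.28, 6.02 and 2.42 at E15 and 0.31, 2.47 and 3.06 at P1.

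**Figure D2:**
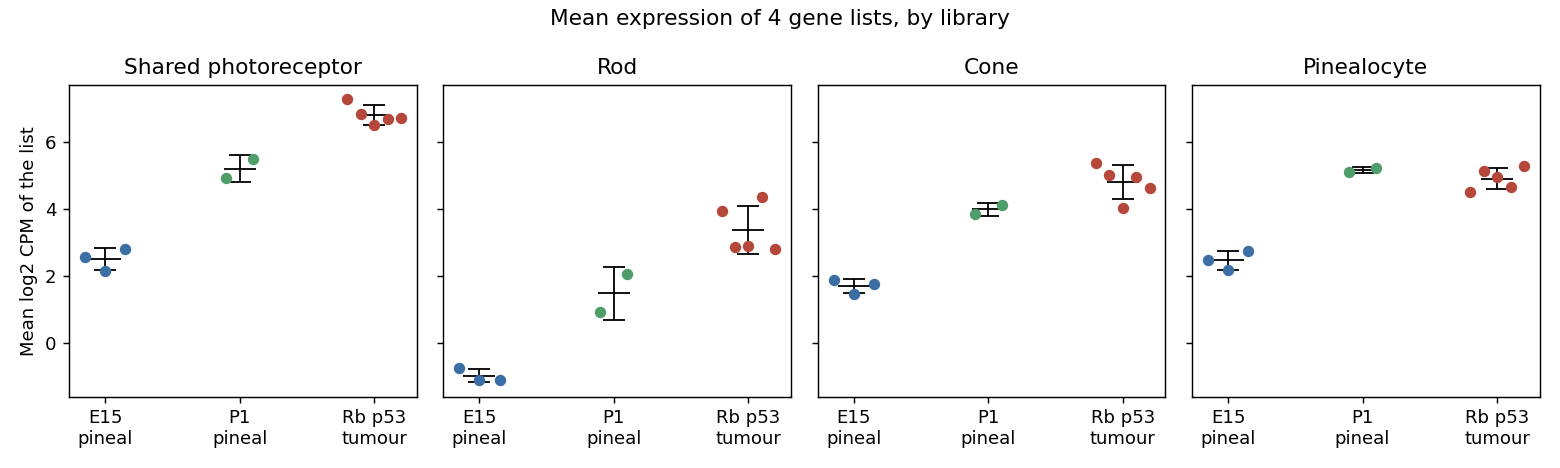
Mean log2 CPM (vertical axis) over the genes of the shared photoreceptor, rod, cone and pinealocyte lists in each library, by group. Each point is a library and the bar shows the mean ± SD. The shared photoreceptor mean is 2.51 in E15 pineal, 5.20 in P1 pineal and 6.81 in the tumours, while the pinealocyte mean is 5.15 in P1 pineal and 4.91 in the tumours.

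Lists of cell division had lower medians at P1, but few of their genes were called and no list was called with an estimated correlation. Of 25 genes of G2 and M phase, Aurka, a mitotic kinase, fell by 1.23 on the log2 scale (SE 0.25, adjusted p = 0.0463), and the other 24 were not called by edgeR in the fit of all 10 libraries. Adjusted over the list alone, all 25 fell. With the replicate number as a block Aurka was not called (adjusted p = 0.138). Cdk1, the main mitotic kinase, had 88.3 ± 16.3 CPM at E15 and 39.5 ± 10.6 CPM at P1 (log2 fold change -1.16, SE 0.26, adjusted p = 0.0637). The list had a camera adjusted p = 4.16e-19, and adjusted p = 0.224 with an estimated correlation. Of 25 S phase genes none was called by edgeR over all genes and 6 fell adjusted over the list alone (camera adjusted p = 1.34e-09, and adjusted p = 0.402 with an estimated correlation). Of 20 replication-dependent histone genes none was called by edgeR over all genes and 9 fell adjusted over the list alone (camera adjusted p = 6.31e-09, and adjusted p = 0.402 with an estimated correlation). Ribosome biogenesis genes, 28 in number, had no call by edgeR over all genes or adjusted over the list alone and a median log2 fold change of -0.30 (camera adjusted p = 0.00114, and adjusted p = 0.672 with an estimated correlation). The call of Aurka was lost without each of the 5 pineal libraries in turn, with an adjusted p of 0.147, 0.140 and 0.0990 without E15 libraries 1, 2 and 3 and of 0.345 and 0.0601 without P1 libraries 1 and 2, within a range of 1.78e-04 to 0.345 over its alternatives.

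Other tools called more of these genes lower at P1. In the simulations of this comparison limma voom made 0 false calls among 47 and edgeR 2 among 54. DESeq2 made 97 false calls among 192. It called lower Cdk1 (adjusted p = 0.00149), the mitotic kinesin gene Kif20a (0.00295), the replication genes Gins1 (0.00555), Mcm3 (0.0438) and Cdc45 (0.0421) and the histone genes Hist1h3a (0.0352), Hist1h3b (0.0308) and Hist2h2ac (0.0143). limma voom called Cdk1 (0.00669), Kif20a (0.00799), Mcm3 (0.0259) and the same histone genes (0.0284, 0.0259 and 0.0206), a fit on both ages alone called Cdk1 (0.0438) and Kif20a (0.0418), and the FPKM fits called Cdk1 and Gins1. Over alternatives the adjusted p ranged from 0.00149 to 0.489 for Cdk1, 0.00295 to 0.513 for Kif20a, 0.00555 to 0.644 for Gins1, 0.0259 to 0.803 for Mcm3, 0.0421 to 0.804 for Cdc45, 0.0284 to 0.712 for Hist1h3a, 0.0259 to 0.790 for Hist1h3b and 0.0143 to 0.651 for Hist2h2ac.

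A few oncofetal and erythroid genes fell between E15 and P1. Among 24 oncofetal let-7 targets, Hmga2, a chromatin protein of embryonic cells, fell (log2 fold change -3.67, SE 0.49, adjusted p = 0.00752), as did the RNA-binding protein gene Igf2bp1 (-2.65, SE 0.52, adjusted p = 0.0389), and 4 fell adjusted over the list alone. That list had a camera adjusted p = 9.55e-07, and adjusted p = 0.0391 with an estimated correlation. Of 12 erythroid genes, the embryonic globin genes Hbb-y and Hba-x fell (log2 fold changes -11.72, SE 1.06, and -10.47, SE 1.13), and 5 fell adjusted over the list alone (camera adjusted p = 7.26e-11, and adjusted p = 0.0547 with an estimated correlation). Hbb-y had 136 ± 60.4 CPM at E15 and 0.0368 ± 0.0521 CPM at P1. With the replicate number as a block the adjusted p of Hmga2, Igf2bp1, Hbb-y and Hba-x was 0.0599, 0.148, 0.0726 and 0.0891. Without P1 library 1 the adjusted p of Hmga2, Igf2bp1 and Hba-x was 0.117, 0.335 and 0.0888, and without P1 library 2 that of Hmga2, Igf2bp1, Hbb-y and Hba-x was 0.0748, 0.1501, 0.0601 and 0.0710. Without E15 library 1 the values of Igf2bp1, Hbb-y and Hba-x were 0.134, 0.0618 and 0.0862, without E15 library 2 they were 0.167, 0.0545 and 0.0670, and Igf2bp1 had 0.107 without E15 library 3. Over their alternatives the adjusted p ranged from 2.04e-15 to 0.117 for Hmga2, 6.14e-09 to 0.335 for Igf2bp1, 1.85e-24 to 0.0726 for Hbb-y and 8.88e-16 to 0.0891 for Hba-x. The number of let-7 targets called was 1 without each E15 library and 0 without each P1 library, and that of erythroid genes 0 without E15 library 1, E15 library 2 or P1 library 2 and 1 without P1 library 1.

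Genes of skin epidermis, a list added after the data were seen, were lower at P1 as well. Of 18, 10 fell and none rose, with a median log2 fold change of -5.36, and 16 fell adjusted over the list alone. Calm4, a calmodulin-like gene of keratinocytes, fell by 10.41 (SE 1.36, adjusted p = 0.00712), from 38.1 ± 33.4 to 0.0246 ± 0.0347 CPM. The list gave a camera adjusted p = 3.18e-30, and adjusted p = 0.00964 with an estimated correlation. Genes of skeletal muscle and of bone and cartilage, the other lists added then, had no call among 15 and 14 genes by edgeR over all genes, and 1 muscle gene was higher adjusted over the list alone. The number of called epidermis genes was 6 without E15 library 1 or E15 library 2, 3 without P1 library 1 and 1 without P1 library 2. Without P1 library 2 the call of Calm4 was lost (adjusted p = 0.0710, in a range of 4.08e-12 to 0.0710 over its alternatives).

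Among synaptic vesicle genes, 4 of 21 rose and 5 did so adjusted over the list alone, among them the synaptophysin gene Syp by 2.44 (SE 0.31) and the ribbon synapse calcium channel gene Cacna1f by 4.28 (SE 0.56) (camera adjusted p = 1.49e-06, and adjusted p = 0.386 with an estimated correlation). Of 15 astrocyte genes, the intermediate filament gene Gfap rose by 6.87 (SE 1.31), from 0.418 ± 0.227 to 50.5 ± 59.8 CPM, and 6 rose adjusted over the list alone (camera adjusted p = 0.00102, and adjusted p = 0.621 with an estimated correlation). Of 15 genes of other retinal cells, 1 rose, and 3 rose adjusted over the list alone (camera adjusted p = 0.0105, and adjusted p = 0.402 with an estimated correlation). The interferon list of 17 genes and the antigen presentation list of 14 had no call by edgeR in the fit of all 10 libraries, over all genes or adjusted over the list alone, and median log2 fold changes of 1.07 and 0.72 (camera adjusted p = 0.0137 and 0.0230, each with adjusted p = 0.858 with an estimated correlation). An edgeR fit on both ages alone called the interferon genes Oasl2 (log2 fold change 1.87, adjusted p = 0.0138) and Ifit1 (1.86, 0.0392) higher. On log2(FPKM + 1) the log2 fold change of Cacna1f was 0.85 (adjusted p = 0.380) and that of Gfap 3.07 (0.162). With the replicate number as a block the adjusted p of Gfap was 0.127. Its log2 fold change was 4.25 without P1 library 2. Without P1 library 2 the adjusted p of Syp and Gfap was 0.0550 and 0.202, and the retinal, interferon and antigen presentation lists had 0.229, 0.101 and 0.308. Without E15 libraries 1, 2 and 3 the adjusted p of Gfap was 0.153, 0.143 and 0.107, and without E15 library 3 the interferon and antigen presentation lists had 0.0557 and 0.140. Over alternatives the adjusted p ranged from 7.98e-09 to 0.0550 for Syp, 5.23e-10 to 0.404 for Cacna1f and 1.03e-07 to 0.202 for Gfap, and from 3.70e-05 to 0.402, 0.00872 to 0.858 and 0.00279 to 0.858 for the 3 lists. The synaptic vesicle genes called were 2 without E15 library 1, E15 library 2 or P1 library 1, and 1 without P1 library 2.

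The remaining lists had no camera call between P1 and E15. Wnt3a, a signalling gene of the dorsal midline, fell by 4.24 as the single call of 19 neural progenitor genes, and the glucose transporter gene Slc2a1 fell by 1.37 as the single call of 17 hypoxia genes. Neither list had a call without E15 library 1, E15 library 2, P1 library 1 or P1 library 2, nor the hypoxia list without E15 library 3. Adjusted over the list alone, 1 progenitor gene fell, and 1 hypoxia gene rose and 1 fell. The p53 target, microRNA host, brain neuron, oligodendrocyte, ependyma and choroid plexus, microglia, lymphocyte, endothelium, mural, fibroblast and meninges, pigment cell, immediate early and mitochondrial lists had no called member by edgeR. Adjusted over the list alone, 2 p53 targets were higher and 3 lower, and 1 brain neuron gene was lower. The endothelium and fibroblast and meninges lists had median log2 fold changes of 0.03 and 0.12. By fry, 8 of the lists that camera called between the ages were not called: S phase (adjusted p = 0.137), histone (0.122), ribosome biogenesis (0.374), synaptic vesicle (0.0970), astrocyte (0.327), other retinal cells (0.159), and interferon and antigen presentation (0.675 each). Over alternatives the adjusted p ranged from 4.07e-13 to 0.402 for S phase, 1.15e-10 to 0.402 for histone, 0.00118 to 0.672 for ribosome biogenesis, 2.66e-07 to 0.386 for synaptic vesicle and 5.11e-04 to 0.621 for astrocyte genes. Median, mean and camera direction differed in sign for the lymphocyte, ependyma, pigment cell, endothelium and microRNA host lists.

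Between E15 and P1, 339 of 21806 genes were called by edgeR, 245 higher and 94 lower at P1, of which 234 and 92 changed by at least 1 on the log2 scale. The largest increases were those of the tachykinin gene Tac4, by 9.98 (SE 1.05), the trypsin inhibitor gene Spink4, by 8.38 (SE 1.06), and Pde6g. With a replicate number as a block, 119 genes were called, and the adjusted p of Spink4 was 0.0649, in a range of 6.14e-09 to 0.0649 over its alternatives. The number of calls was 108 without E15 library 1, 110 without E15 library 2, 115 without P1 library 1 and 71 without P1 library 2, and it was 1314 with DESeq2, 1856 with limma voom and 1208 in a fit on both ages alone. Without P1 library 2 and tumour 89, which hold markers of other tissues, 267 genes were called and 163 of the 339 were among them.

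The comparison of Rb p53 tumours with pineal gland asked how these tumours differ from E15 and P1 pineal gland. No later age of the gland was in the baseline, and the labels give no age of the tumours at collection. Differences of age are therefore part of this comparison. The tumours had more transcripts of photoreceptor genes and of cell division and fewer of neural progenitors, blood vessels and connective tissue. Trp53 and Rb1 fell against the mean of E15 and P1 pineal, with log2 fold changes of -2.46 (SE 0.21, adjusted p = 3.14e-05) and -0.96 (SE 0.15, adjusted p = 5.24e-04). Crx rose by 1.55 (SE 0.33, adjusted p = 0.00275). Dgcr8 rose by 0.80 (SE 0.21, adjusted p = 0.00955), and Myc had a log2 fold change of -1.18 (SE 0.48, adjusted p = 0.0575). The largest increases included Hoxc8, a homeobox gene of trunk positional identity, by 10.53 (SE 0.95), from 0.0680 ± 0.0651 CPM at E15 (SD, n = 3) and 0 at P1 (n = 2) to 20.3 ± 9.80 CPM in the tumours (SD, n = 5). Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 activator Arf, rose by 9.36 (SE 0.66), from 0.132 ± 0.0791 and 0.103 ± 0.145 CPM to 77.6 ± 23.8 CPM. The immunoglobulin gene Igha had no count in the pineal libraries and 29.2 ± 41.6 CPM in the tumours, at least 1974-fold higher on average. Single tumours spread widely, with Igha at 100.1 CPM in tumour 88, 33.4 in tumour 98 and 2.86 to 5.59 in tumours 53, 55 and 89. Ankrd33, an ankyrin gene of photoreceptors, rose by 8.48 (SE 0.49) and Pgc, the pepsinogen C gene by 8.05 (SE 0.45). Mobp, a myelin gene, rose by 8.66 (SE 2.05) to 37.3 ± 73.6 CPM, with 169 CPM in tumour 89, which also has the highest brain neuron and oligodendrocyte lists, and 0.757 to 8.28 CPM in the other tumours.

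The largest decreases were those of epithelial, choroid plexus and mast cell genes. The keratin gene Krt4 and the desmosomal gene Dsg1a had no count in the tumours, at least 6964-fold and at least 3559-fold lower than the pineal mean of the 2 ages. That mean rests on E15, where epidermis genes were high: Krt4 had 183 ± 112 CPM at E15 and 4.78 ± 6.55 at P1, Dsg1a 94.0 ± 63.3 and 2.05 ± 2.77, and Krt14 286 ± 219 and 7.91 ± 11.02. Krt14 (log2 fold change -11.50, SE 1.56), the transthyretin gene Ttr (-11.40, SE 1.08) and the mast cell protease gene Cpa3 (-9.65, SE 1.17) fell as well. Ttr, an abundant product of the choroid plexus, had 3342 ± 1026 CPM at E15, 1689 ± 160 CPM at P1 and 0.907 ± 1.28 CPM in the tumours. The call of Dgcr8 was lost on FPKM values (adjusted p = 0.214) and with the replicate number as a block (0.0877), within a range of 0.00246 to 0.214 over its alternatives, and that of Mobp on log2(FPKM + 1) (0.105) and with the block (0.0740), within 0.00132 to 0.105. The log2 fold changes of Dgcr8 and Mobp were 0.33 and 1.91 on log2(FPKM + 1) and 0.83 and 8.71 with the block. Myc was called lower in 10 alternatives, with an adjusted p of 0.0288 with DESeq2, 0.0211 with limma voom, 0.00445 to 0.0120 on FPKM values, 0.0427 with a stricter filter, 0.0377 against E15 alone, 0.0446 without tumour 55, 0.0275 without tumour 89 and 0.0402 without tumours 88 and 89, within 0.00445 to 0.271 over its alternatives.

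Photoreceptor genes rose in the tumours. Of 24 genes shared by rods and cones, 21 rose and 2, Crb1 and Prdm1, fell, with the same counts adjusted over the list alone. Of these 24, 1 fell without E15 library 1, E15 library 3, P1 library 1, tumour 53, tumour 88 or tumour 89, and none fell without P1 library 2. Impg2, of the matrix between photoreceptors, rose from 15.3 ± 6.53 CPM at E15 and 154 ± 14.8 CPM at P1 to 1891 ± 514 CPM, a log2 fold change of 5.28 (SE 0.35, adjusted p = 1.19e-05). Cplx4 rose by 5.74 (SE 0.31) and Tulp1 by 3.15 (SE 0.21). Of 20 rod genes, 15 rose and 1 fell, and 16 and 1 did adjusted over the list alone, with Rom1 higher by 3.65 (SE 0.16), Cngb1 by 3.71 (SE 0.29) and Pde6g by 2.73 (SE 0.27). The rod transcription factor genes Nrl and Nr2e3 rose by 4.02 and 6.32. Of 17 cone genes, 11 rose and 3 fell, over all genes and adjusted over the list alone, with the transducin genes Gngt2, Gnat2 and Gnb3 higher by 5.72 (SE 0.42), 5.61 (SE 0.43) and 3.47 (SE 0.29). The shared, rod and cone lists had camera adjusted p of 2.36e-07, 1.77e-05 and 0.00727, and each had adjusted p = 0.365 with an estimated correlation. By fry, which asks whether a list moves on balance in one direction, the adjusted p was 1.35e-05, 7.99e-05 and 4.10e-05.

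Pinealocyte genes rose against the mean of both ages: of 19, 13 rose and 1 fell, and 13 and 2 did adjusted over the list alone. The nicotinic receptor genes Chrna3 and Chrnb4 rose by 4.14 (SE 0.34) and 3.74 (SE 0.33), Adrb1 by 2.19 (SE 0.19), and Tph1, the first enzyme of serotonin synthesis, by 2.13. The list had a camera adjusted p = 0.00627, and adjusted p = 0.365 with an estimated correlation. Aanat had 0.375 ± 0.232 CPM in the tumours against 14.4 ± 2.68 CPM in P1 pineal and 0.0529 ± 0.0223 CPM in E15 pineal.

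Against P1 pineal alone, 15 shared photoreceptor genes rose and 2 fell, and 16 and 2 did adjusted over the list alone (camera adjusted p = 1.04e-04, and adjusted p = 0.438 with an estimated correlation). For rod genes, 9 rose and 2 fell against P1, and 10 and 2 did adjusted over the list alone (camera adjusted p = 0.00408, and adjusted p = 0.486 with an estimated correlation). For cone genes, 8 rose and 2 fell, and 10 and 3 adjusted over the list alone, without a list call (camera adjusted p = 0.0864). For pinealocyte genes, 5 rose and 2 fell, and 5 and 1 adjusted over the list alone, without a list call (camera adjusted p = 0.494). Aanat and Pde6g fell against P1, with log2 fold changes of -5.26 (SE 0.59) and -1.09, and Crx had one of 0.41 (adjusted p = 0.446, in a range of 5.87e-05 to 0.446 over its alternatives). Gnat1 and Rcvrn, encoding rod transducin and recoverin, rose by 6.66 (SE 1.40) and 5.51 (SE 1.54) against P1, among the largest of these changes. Their P1 means were low, at 0.190 and 0.333 CPM. The tumours spread widely, at 19.5 ± 24.1 and 15.3 ± 13.3 CPM (SD, n = 5).

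Genes of cell division rose as a group. All 25 genes of G2 and M phase rose, as did 24 of 25 S phase genes, and the same numbers rose adjusted over the list alone. Cdk1 rose from 88.3 ± 16.3 CPM at E15 and 39.5 ± 10.6 CPM at P1 to 311 ± 53.3 CPM, a log2 fold change of 2.40 (SE 0.19, adjusted p = 2.08e-05). The replication genes Cdt1 and Cdc45 rose by 2.80 (SE 0.21) and 2.56 (SE 0.19). The S and the G2 and M lists had camera adjusted p of 7.10e-10 and 1.54e-09, and each had adjusted p = 0.365 with an estimated correlation. Of 28 ribosome biogenesis genes, 18 rose and none fell, over all genes and adjusted over the list alone, such as the nucleolar genes Nop56 by 1.58 (SE 0.12) and Nop58 by 1.42 (SE 0.10) (camera adjusted p = 1.64e-04, and adjusted p = 0.466 with an estimated correlation). Of 20 replication-dependent histone genes, 14 rose, and 15 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00179, and adjusted p = 0.539 with an estimated correlation). The histone list was not called against E15 pineal alone (adjusted p = 0.120, in a range of 1.79e-05 to 0.539 over its alternatives), and 9 histone genes rose without P1 library 1. In tumour 89 the mean of the G2 and M list was 6.96 log2 CPM, against 7.56 to 7.74 in the other tumours.

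Neural progenitor genes fell: 17 of 19 were lower and none higher, over all genes and adjusted over the list alone. Zic1, a transcription factor of the dorsal neural tube, fell from 366 ± 51.4 and 401 ± 102 CPM to 19.2 ± 6.43 CPM, a log2 fold change of -4.31 (SE 0.28, adjusted p = 1.19e-05). The receptor gene Notch2 (-3.96, SE 0.32), the homeobox gene Msx2 (-6.10, SE 0.51) and the progenitor gene Sox2 (-3.21) fell as well. The list had a camera adjusted p = 3.72e-07, and adjusted p = 0.365 with an estimated correlation. Of 24 oncofetal let-7 targets, 6 rose, with Mycn higher by 2.23 and Lin28a by 2.67, and 13 fell, with log2 fold changes of -9.36 for Igf2bp1 and -7.34 for Hmga2, without a list call (camera adjusted p = 0.127). Adjusted over the list alone, 7 rose and 13 fell. Of 27 p53 targets, 11 rose, with the cell cycle inhibitor gene Cdkn1a higher by 2.31 and Mdm2 by 0.90, and 5 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.398). Of 15 microRNA host transcripts, 3 rose and 4 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.398), and the number that fell was 2 without P1 library 2, 7 without tumour 89 and 2 without tumour 98.

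Markers of blood vessels, connective tissue and blood fell in the tumours. All 15 endothelial genes fell, such as the receptor gene Tek from 100.3 ± 14.04 and 96.4 ± 12.9 CPM to 7.96 ± 3.25 CPM (log2 fold change -3.63, SE 0.31, adjusted p = 2.89e-05). Of 15 fibroblast and meninges genes, 14 fell and none rose, among them Igf2 (-8.36, SE 0.80) and Foxc1 (-4.62, SE 0.62), and 15 fell adjusted over the list alone. Of 12 erythroid genes, 11 fell, such as the anion exchanger gene Slc4a1 (-6.91, SE 0.61), with a median log2 fold change of -6.67, or -6.53 with genes without a count in the tumours at their bound. Of 13 pigment cell genes, 12 fell, such as Mitf (-3.68, SE 0.17), and Mc1r rose by 2.07. Of 14 ependyma and choroid plexus genes, 9 fell, such as Kcnj13 (-7.31, SE 0.86), and 1 rose. Of 11 mural genes, 5 fell, such as Notch3 (-4.06, SE 0.51). Counts adjusted over the list alone were the same for the endothelium, pigment, ependyma and mural lists, and 11 erythroid genes fell and 1 rose. The endothelium, fibroblast, erythroid, pigment and ependyma lists had camera adjusted p of 5.07e-07, 4.05e-06, 2.25e-05, 5.67e-04 and 0.00557, each with adjusted p = 0.365 with an estimated correlation. The mural list had 0.0397, and adjusted p = 0.531 with an estimated correlation. It was lost without E15 library 1 (0.0529), P1 library 2 (0.0614), tumour 53 (0.0509) or tumour 89 (0.0839) and against E15 alone (0.0925), in a range of 0.00268 to 0.531 over its alternatives.

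The lists added after the data were seen fell too. Of 18 epidermis genes, 17 fell and the epithelial factor gene Grhl3 rose; of 15 skeletal muscle genes, 11 fell and Myog rose; and of 14 bone and cartilage genes, 9 fell, each over all genes and adjusted over the list alone. Their camera adjusted p were 1.83e-06, 0.0108 and 0.00325, and adjusted p = 0.216, 0.386 and 0.216 with an estimated correlation. Most of the epidermis change lies between the ages, with a mean log2 CPM of 6.28 at E15, 0.31 at P1 and -1.44 in the tumours, and against P1 alone 7 epidermis genes fell and 1 rose, with the same counts adjusted over the list alone. Without P1 library 2, 7 skeletal muscle genes fell, and without tumours 88 and 89 that list was not called (adjusted p = 0.0954, in a range of 1.18e-04 to 0.386 over its alternatives).

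Genes of the interferon response and of antigen presentation rose. All 17 interferon genes rose, such as Usp18 by 4.79 (SE 0.73), Ifit1 by 4.78 (SE 0.81) and Irf7 by 5.20 (SE 0.94), and so did all 14 antigen presentation genes, such as the class I genes H2-K1 by 4.41 (SE 0.58) and H2-D1 by 3.96 (SE 0.54) and the class II gene H2-Ab1 by 5.84 (SE 0.81). The numbers were the same adjusted over the list alone. H2-K1 had 12.9 ± 1.68 CPM at E15, 20.8 ± 9.09 CPM at P1 and 350 ± 242 CPM in the tumours. The lists had camera adjusted p of 1.79e-04 and 2.25e-05, and adjusted p = 0.529 and 0.465 with an estimated correlation. Of 14 lymphocyte genes, 8 rose, with the T cell genes Cd8a and Cd3d higher by 3.95 and 5.30, over all genes and adjusted over the list alone, without a list call (camera adjusted p = 0.136), and 4 rose without tumour 88 and without tumour 98. Of 17 microglia and macrophage genes, 7 rose and 3 fell (camera adjusted p = 0.425), with 4 higher without P1 library 1. Tumour 88 had the highest means of the interferon, antigen presentation and lymphocyte lists, at 6.87, 7.39 and 1.33 log2 CPM, against 3.18 to 4.75, 3.88 to 6.20 and -2.53 to -0.31 in the other tumours. Without tumours 88 and 89, 17 interferon and 14 antigen presentation genes rose.

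Neuronal and glial lists moved in both directions. Of 21 synaptic vesicle genes, 10 rose, with the vesicular glutamate transporter gene Slc17a7 higher by 4.12, and 1 fell (camera adjusted p = 0.0771). Of 20 brain neuron genes, 1 rose and 5 fell, and none rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0563). Of 15 astrocyte genes, 6 rose and 3 fell (camera adjusted p = 0.840), and of 14 oligodendrocyte genes, 6 rose and 3 fell (camera adjusted p = 0.893; its direction was down while the median and mean log2 fold changes were 0.77 and 1.01). Of 15 genes of other retinal cells, 4 rose and 5 fell (camera adjusted p = 0.398), and of 17 hypoxia genes, 5 rose and 4 fell (camera adjusted p = 0.770). Adjusted over the list alone, 5 retinal genes rose and 5 fell, and the synaptic, astrocyte, oligodendrocyte, microglia and hypoxia counts were the same. Tumour 89 had a mean of 4.92, 6.78 and 4.88 log2 CPM for the brain neuron, astrocyte and oligodendrocyte lists, the highest of the 5 tumours. Without it 15 brain neuron, 7 synaptic vesicle, 6 astrocyte and 5 oligodendrocyte genes fell and 3 oligodendrocyte genes rose, and 3 oligodendrocyte genes rose without each E15 library and without P1 library 1. Without E15 library 1, 2 synaptic vesicle genes fell.

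Of 17 immediate early genes, which rise with tissue handling, 11 rose, such as Junb by 2.67 (SE 0.29) and Arc by 5.26 (SE 0.79) (camera adjusted p = 0.00871, and adjusted p = 0.465 with an estimated correlation). Of 13 mitochondrial transcripts, 6 fell, such as mt-Nd2 (-2.69, SE 0.29) and mt-Nd4 (-2.30, SE 0.28) (camera adjusted p = 0.0121, and adjusted p = 0.529 with an estimated correlation). Both counts were the same adjusted over the list alone.

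**Figure D3:**
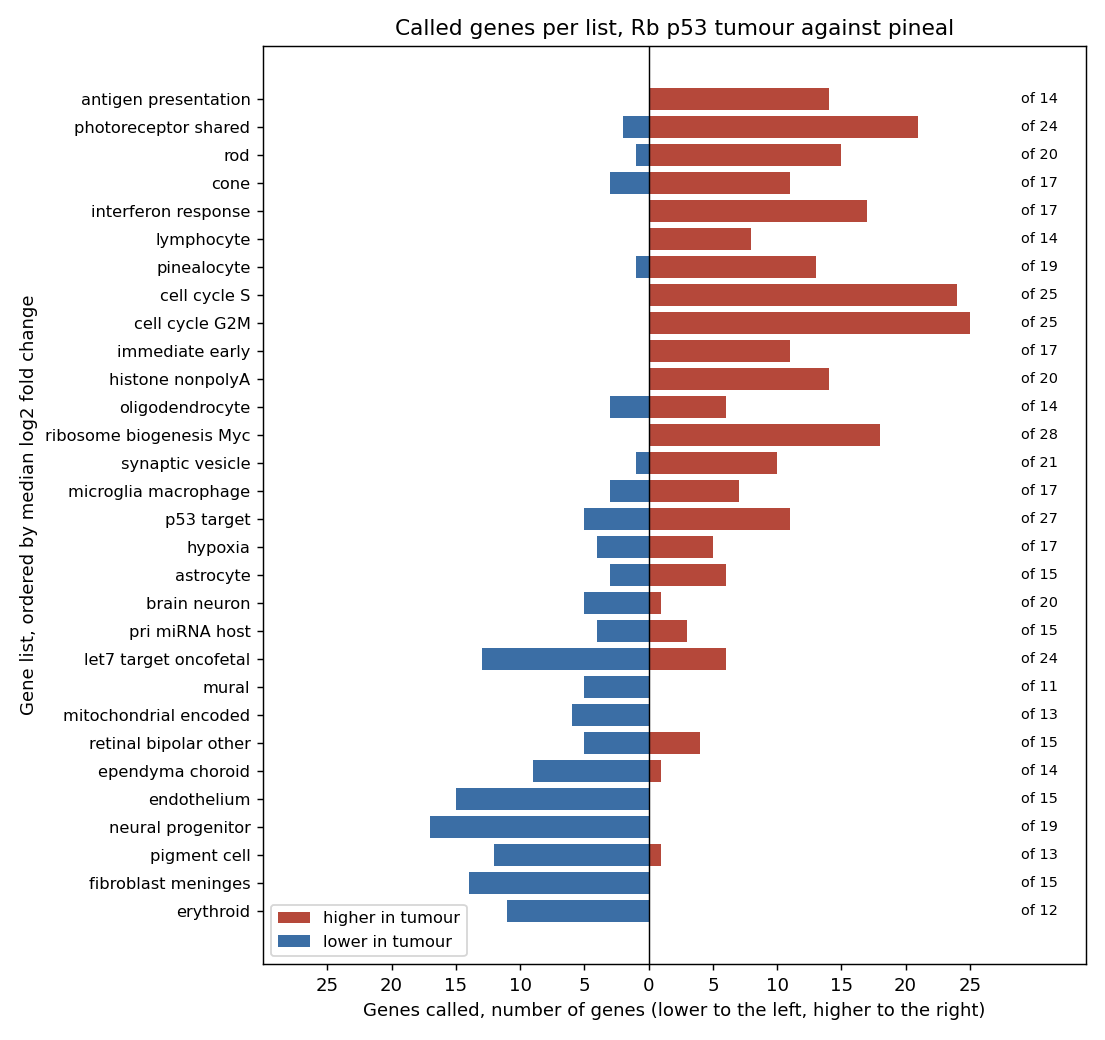
Number of genes called higher (right) and lower (left) in Rb p53 tumours (n = 5) than in pineal gland (n = 5), for each of the 30 fixed gene lists (vertical axis, ordered by median log2 fold change), with the number measured beside each bar. All 14 antigen presentation genes are higher and 11 of 12 erythroid genes are lower.

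Between tumours and pineal gland, 13146 of 21806 genes were called by edgeR, 6878 higher and 6268 lower in the tumours, of which 4351 and 5157 changed by at least 1 on the log2 scale. Against E15 alone 12378 genes were called and against P1 alone 9684, with 4178 higher and 4465 lower against both and 19 called in opposite directions. With the replicate number as a block, 7690 genes were called. There the tumours had the coding of replicate 1, so they were compared with pineal levels fitted for that number. Tissue, genotype and age of the animals differ together between these groups, and the labels give the age of induction of the tumours and not their age at collection.

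The changes between E15 and P1 were compared with those between tumour and pineal, to ask whether genes that rose toward P1 also rose in tumours. Of the genes called in both comparisons, 194 were higher at P1 and higher in tumours, 20 were higher at P1 and lower in tumours, 13 the reverse and 51 lower in both. Independent calls would give 77.3, 70.4, 29.6 and 27.0, while simulations with no group difference gave 0 for each, which is no test of the overlap since such data hold almost no calls. The correlation of the log2 fold changes across genes was 0.28 and their covariance 0.72, against -0.18 and -0.0705 in the simulations. Against P1 alone, where the shared P1 libraries pull the changes apart, the numbers were 120, 41, 16 and 20 beside 52.6, 56.2, 20.2 and 21.6, with a correlation of 0.0026 and a covariance of 0.0066 against -0.68 and -0.36 in the simulations. With 2 P1 libraries the pineal libraries could not be divided into parts of at least 2 libraries each. In the simulations shared controls pulled the changes apart. For genes higher in both, the 120 beside 52.6 against P1 alone argue against shared controls as the source of the excess. Genes lower in both had no such excess against P1 alone (20 beside 21.6), where the shared libraries pull the changes apart and could hide one. Against the mean of both ages they numbered 51 beside 27.0. There the shared controls on balance work against such an excess (simulated correlation -0.18). The E15 libraries enter both comparisons with the same sign, so for single genes they could still add to the 51. Their part in it stays open.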

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

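Single tumours stood apart from the other 4 in 8 of 109 measures, by a test of the gap to the nearest tumour over the range (threshold 0.71). Chance alone marks about 1 in 20 groups, so several of these may be chance. Values are log2 CPM in 1 library, and each group has 5 tumours. Dgcr8, of the microRNA processing complex, was 7.108 in tumour 53 and 5.99 to 6.25 in the others. Tumour 88 had -2.202 for the mast cell gene Cpa3, at 0.170 CPM (the others have no count and share the value -4.41, so a few reads suffice) and -1.044 for the choroid plexus gene Kcnj13 (others -3.91 to -3.28). Tumour 89 had 6.764 for the cone transducin gene Gngt2 (others 8.39 to 8.68), 6.778 for the nicotinic receptor gene Chrna3 (8.02 to 8.29) and 8.08 for the mitotic kinesin gene Kif11 (8.65 to 8.79). Its mean was 6.955 for the G2 and M phase list (others 7.56 to 7.74) and 4.923 for the brain neuron list (others 0.32 to 1.55).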

How the results depend on the processing

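The fits without P1 library 2 and tumour 89 (267 genes called between E15 and P1), without tumours 88 and 89 (14564 between tumour and pineal) and without epidermis and erythroid genes (321 between E15 and P1) were tests chosen only after the result was seen. The number of genes called between E15 and P1 depended on the method, while the direction of lineage genes such as Tulp1, Pde6g and Aanat did not. Against 339, the number was 1314 with DESeq2, 1856 with limma voom, 581 on log2(FPKM + 1), 610 on log2(FPKM + 0.1), 1208 in a fit on both ages alone and 119 with the replicate number as a block. The share called higher at P1 was 72.3%, against 85.8% with a stricter filter, 48.8% with DESeq2, 56.6% with limma voom, 51.3% and 50.2% on the FPKM values and 55.9% on genes of mean FPKM of at least 1. With a library left out, 71 (without P1 library 2) to 239 (without E15 library 3) genes were called, with 108 without E15 library 1, 110 without E15 library 2 and 115 without P1 library 1. The share called higher was then 80.6% without E15 library 1, 81.8% without E15 library 2, 59.0% without E15 library 3, 95.7% without P1 library 1 and 90.1% without P1 library 2. The cause was not tested. Dgcr8, not called between the ages, changed sign on log2(FPKM + 1) (0.0445, also at mean FPKM of at least 1) and on log2(FPKM + 0.1) (0.0478).

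For tumour against pineal, 7690 genes were called with the replicate block in place of 13146, and 11261 (without P1 library 1) to 14357 (without tumour 89) with a library left out. Pde6g changed sign against P1 pineal alone, at -1.093. P21 pineal alone as the baseline and a fit on only the tumours induced at E15 were not run, since those libraries or labels could not be tied to columns. A fit on the compared groups alone is the fit itself here. Depth was not varied here, and genes of few counts were left out by the filter, which kept 21806 of 37450 genes.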

Other observations

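The tests of a chromosome segment, of skin in the dissections, of the share of pineal cells and of other divisions of the libraries were chosen only after the results were seen, as were the genes of the next paragraphs. Hoxc genes, which mark trunk position, rose in the tumours: 6 of 7 tested members of the cluster on chromosome 15 (102921103 to 103036852), while of 12 tested Hoxa, Hoxb and Hoxd genes none rose and 4 fell. These 4 were already low at P1, such as Hoxd1 at 1.32 CPM at E15, 0.0380 at P1 and 0.0314 in the tumours, or Hoxb2 at 0.826, 0.0380 and 0.00881. Hoxa5 had 1.05, 0.164 and 0.0229 CPM, so its tumour mean also lay well below P1. Hoxc5 rose by 7.01 on the log2 scale, to 42.7 ± 22.3 CPM (SD, n = 5), Hoxc6 by 7.30 and Hoxc4 by 5.25, while Hoxc9 had no count in pineal and 12.1 ± 4.61 CPM in the tumours. The noncoding RNA gene H19 fell, at -9.08 (SE 1.40), as did the cyclin gene Ccnd1, at -3.36, which acts through Rb.

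Of 4 enzyme genes of the melatonin pathway, Aanat alone was called by edgeR between tumours and P1 pineal, at -5.26 (SE 0.59, adjusted p = 2.78e-04). Asmt had a log2 fold change of -1.15 (adjusted p = 0.108), Ddc of 1.24 (0.278) and Tph1 of 0.38 (0.682). Xist, from the inactive X, and the Y gene Ddx3y were both present in each pineal library, at 109 to 297 and 39.3 to 68.8 CPM. Tumours 53, 88 and 98 had 17.6, 108 and 22.2 CPM of Ddx3y and 0.484, 0.633 and 0.169 CPM of Xist, and tumours 55 and 89 had 137 and 93.9 CPM of Xist and no count of Ddx3y.

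Genes around Mycn, a growth-promoting transcription factor on chromosome 12 (12936093 to 12941914), were high in tumours 53 and 89. The median difference from pineal over 25 genes within 5 Mb was 1.45 and 1.91 log2 units there and 0.70, 0.0264 and 1.11 in tumours 55, 88 and 98, with Mycn at 352, 330, 142, 105 and 243 CPM in that order. Of 10187 overlapping runs of as many genes on other chromosomes, 0 were as high in both tumours. Tumours 53 and 89 were picked for a high region, so this count partly repeats the pattern. The median difference over all expressed genes was 0.204 and 0.197 there, which argues against a shift of the whole library. GC content or gene length is argued against by 86.89% of the median left after correction. Of the region's genes 84% lay above every pineal library in each of tumours 53 and 89 and 64%, 36% and 72% in tumours 55, 88 and 98, but this repeats the pattern and is no test of a gain of the segment. Beyond 40 Mb on chromosome 12 the median was -0.104 and 0.292 in tumours 53 and 89. It was 1.0024, 0.425 and 0.575 in tumours 55, 88 and 98. DNA was not analysed here, so a gain and regulation of the region both stay open.

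Skin epidermis genes such as Krt10 and Krt1 were lower in P1 than in E15 pineal. Krt10 had 638, 358 and 167 CPM in the E15 libraries and 1.67 and 2.44 CPM in the P1 libraries. Some stayed high in P1 library 2. Krt15 had 27.1 and 132 CPM and Krt5 0.172 and 71.2 CPM in P1 libraries 1 and 2, beside 88.7 and 92.5 CPM in E15 library 3. Of the epidermis genes, 94.44% were lower in E15 library 3 than in both other E15 libraries, which skin in the E15 dissections could give. Genes of any 1 epithelium would move together in this way, so this share cannot tell skin from another source. The fibroblast and meninges list had a median log2 fold change of 0.1223, so these cells showed no fall in share from E15 to P1. This cannot decide on a lower share of pineal cells at E15, since other cells could make up the rest. The epidermis and erythroid lists had mean log2 CPM of 6.28 and 6.02 at E15 and 0.31 and 2.47 at P1. Whether skin cells or epithelium of the gland made these transcripts stays open.

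Photoreceptor genes such as Gnat1 and Rcvrn, which had some of the largest changes, were higher in tumours than in P1 pineal. The median log2 fold change of the shared photoreceptor list was 1.83 with RLE scaling as with TMM. The median of all genes moved by only 0.00854 between these scalings, so their comparison decides nothing. A scaling moves all genes of a library alike, so it cannot make the gap between the list and all genes (median 0.0239 with TMM). Whether scaling affects the level of the list itself stays open. Of 80 photoreceptor and pinealocyte genes, 37 were called higher and 8 (10%) lower, among them Aanat. The genes called lower go against a higher share of pineal cells as the whole cause, but 10% is the bound of that test, and this stays open too. Age and genotype of the animals differ as well and stay open as untested.

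Of 100 divisions of the 10 libraries into groups of 5, 1 called as many genes as tumour against pineal, the real division itself, and the largest other one called 1 gene. Each other division put tumours and pineal libraries together on a side, which widens the spread within groups. Since the first principal component sets all tumours apart from all pineal libraries, this outcome was nearly fixed in advance. It cannot tell tissue, genotype and age apart.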
